A study of Homo sapiens with 23 samples.

How the data were processed

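RNA-seq profiles of 23 libraries from U2OS, a human osteosarcoma cell line, were analysed as the authors deposited them. Per the labels' protocols, cDNA was made and amplified from picogram amounts of total RNA by a modified SMARTseq2 method, and libraries were made with the Nextera XT kit. STAR 2.4.1b, Subread 1.4.6-p2 and DESeq2 and the genome build hg19 are named, without roles, in the submitters' processing notes. The gene annotation, the strand setting of the counting and any filter on genes are not given in the sources used here. Reads of a gene and of an overlapping antisense gene, a pseudogene or a near-identical copy may therefore not be told apart, and values of histone genes, mitochondrial genes and BCYRN1 are uncertain in this respect.

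The deposited table holds 30089 rows and 23 sample columns in log2 units, which the authors made as the log2 of the gene count divided by a size factor per library, plus 1. Within each library, the unlogged values were whole multiples of 1 step for 100% of the values above 0, within 0.02 of a read, so the reads per library could be read back. Depth came to 5.34 M to 13.5 M reads per library, with a median of 9.86 M, and 16336 to 18803 genes had a value above 0. These reads are PCR products without molecular identifiers, so depth counts reads and not molecules. Rows without a gene name (67 rows, 0.00235% to 0.00593% of each library) were left out, 209 rows held only zeros, and 2778 rows shared a symbol with another row. A list used the row with the highest mean of such a symbol. The 29 rows named by a number alone were tested but not named. All sample columns of the table were used.

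Groups were taken from the labels: 4 lines of WT genotype (WT.1, WT.2, A10 and D7) and 2 KO lines (B9 and Clone4), each sampled in G0 and in G1/S with repeats R1 and R2, except that WT.1 has only R2 in G1/S. How the cells were brought to either stage, whether the repeats came from separate cultures and how the lines were derived are not stated in the labels. The p-values therefore measure only the spread between these lines. No pair of repeats was identical, and their reads differed by more than counting noise (chi-square per gene of 31.8 to 265). Amplified libraries of 1 culture would also differ in this way, so the repeats were not shown to be separate samples.

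The line was the unit of replication, since genotype was set per line. R1 and R2 were averaged per line and stage. KO and WT lines were then compared with limma 3.58.1 in R 4.3.3, with a prior variance that followed mean expression and Benjamini-Hochberg adjustment, in G0, in G1/S and on the mean of both. Stage was tested on the G1/S minus G0 difference of each line, so that pairs were formed by line, and the interaction was the difference of those differences between KO and WT. Genes with a value above log2(10 + 1) in at least 4 libraries were tested, 15278 in all. An adjusted p under 0.05 was the threshold. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. WT lines were compared with each other by a limma F test over libraries. The 26 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry beside it. Single values were compared by a two-sided exact permutation test over the 15 splits of the 6 lines into 4 and 2.

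The gene lists, the designs and most alternatives were fixed before the data were examined. NEAT1 and MALAT1 were always named. For each comparison, the rule named the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose mean was at least log2(50 + 1) and whose KO lines all lay beyond all WT lines, or, for stage, whose 6 line differences had 1 sign. Where fewer than 10 passed, the 5 highest and 5 lowest by the limma statistic that met the other conditions were named, and stated not to pass. From a gene list with a called member or a list test past the threshold, up to 4 members were named per comparison: called members with the largest change, otherwise those with the highest mean. Some genes that this rule names are not reported here. Pseudogenes and clone-named loci were skipped, 66 of the 2257 eligible genes for stage. Gene types came from the GENCODE annotation of another build, from which no coordinates are printed.

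Data were simulated with the real means and depths of 15278 genes. Each gene was given the median spread of genes of similar expression, and the changed genes had a mean of at least 50 normalized counts. Line differences were the same in both stages, so the simulated stage changes did not vary by line. The genotype test in G0 recovered 91% of 100 genes changed 4-fold and 47% of 100 changed 2-fold. The stage test recovered 100% and 76%. Of the unchanged genes 5 and 6 were called. With no change simulated, 0 genes were called in each of the 7 comparisons. These rates may be too favourable for the real data, in which genes of similar expression differ in spread.

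The alternatives were other filters, a pseudocount of 10, quantile normalization, equal medians, other priors, libraries as replicates with and without line correlation or replicate block, WT.1 and WT.2 as 1 line, single repeats, and leaving out each line or library. Chosen after seeing the data were limma-voom on the recovered reads summed per line, and runs of the lists, of the WT line test and of the KO line agreement without library A10 G1/S R2.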

Results

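The study asked whether NEAT1_1, the short isoform of the long noncoding RNA NEAT1, modulates transcription. It compared U2OS osteosarcoma cells labelled PAS KO with WT control cells. The stages were labelled G0, the name of a resting state, and G1/S, the transition into DNA replication. The 23 libraries comprised 8 WT and 4 KO libraries in G0, and 7 WT and 4 KO libraries in G1/S. They came from 4 WT and 2 KO lines. Depth ranged from 5.34 M to 13.5 M reads per library. The library A10 G1/S R2 stood apart: it had 5.34 M reads and 32.3% of its normalized counts on mitochondrial genes, against 4.05% to 12.8% in the other libraries. The mitochondrial ribosomal RNA MT-RNR2 alone made up 26.9% of that library, against 2.43% to 8.89% in the others.

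NEAT1, the targeted locus, did not pass the threshold between genotypes in either stage, though sizeable differences remain possible. In G0, its log2 level was 9.90 ± 0.18 (SD, n = 4 lines) in WT and 10.07 ± 0.50 (SD, n = 2 lines) in KO, a difference of 0.17 (95% confidence interval -0.34 to 0.69, limma adjusted p = 0.869, exact permutation p = 0.6). In G1/S, the levels were 9.16 ± 0.93 (SD, n = 4) and 8.96 ± 0.43 (SD, n = 2), a difference of -0.19 (-1.38 to 0.99, limma adjusted p = 0.989, exact permutation p = 0.933). The smallest p that 15 splits allow is 0.067, so the permutation test could not pass. Per library, normalized counts ran from 276 in Clone4 G1/S R2 to 2170 in A10 G1/S R2. A gene-level value pools the short and long NEAT1 transcripts, so it does not check the KO label. SMARTseq2 primes on poly(A) tails, and which NEAT1 transcripts this captured was not measured. MALAT1, the neighbouring nuclear RNA, had log2 levels in G0 of 13.41 ± 0.35 (SD, n = 4) in WT and 13.21 ± 0.74 (SD, n = 2) in KO, and in G1/S of 12.50 ± 0.34 and 12.60 ± 0.09.

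**Figure D1:**
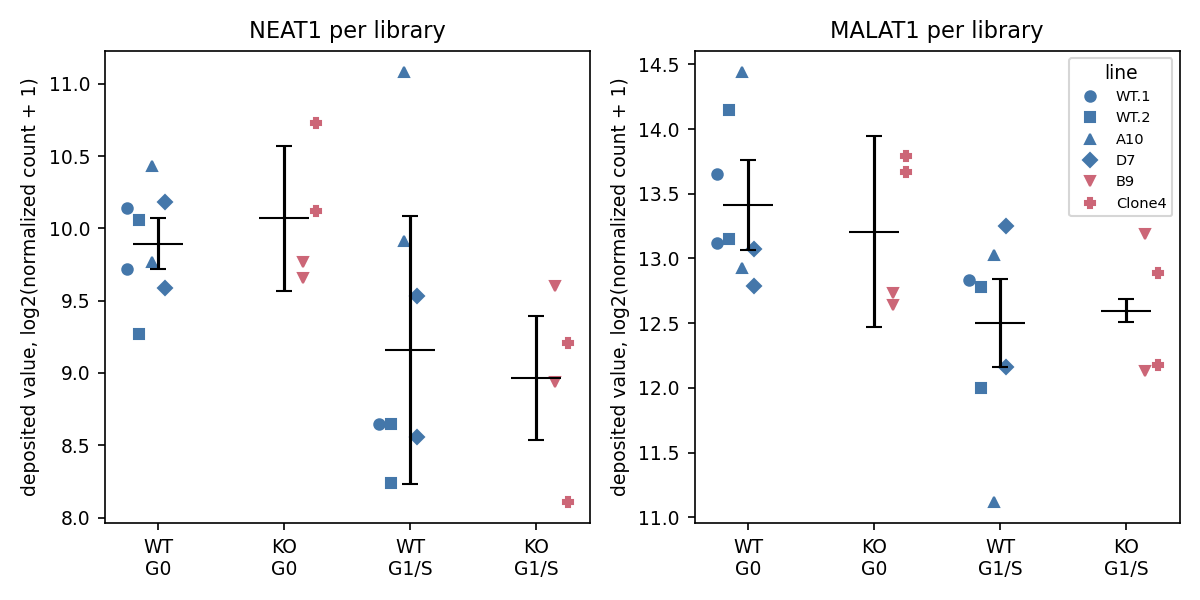
NEAT1 (left) and MALAT1 (right) per library, as the deposited log2(normalized count + 1), with 1 symbol shape per line, WT in blue and KO in red; black bars show the mean and SD over lines. WT and KO lines overlap in both stages, and the highest NEAT1 value, 11.08, is that of A10 G1/S R2.

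The genotype comparison in G0 asked which genes differed between KO and WT cells labelled G0. SCG5, which encodes a secretory granule chaperone, was 7.46-fold lower in the KO lines, at 5.64 ± 0.17 (SD, n = 2) against 8.54 ± 0.16 (SD, n = 4) on the log2 scale. It was the 1 gene of 15278 past the threshold (limma log2 fold change -2.90, SE 0.22, adjusted p = 0.00622), and 1213 genes had an unadjusted p under 0.05. Without library WT.1 G0 R1, B9 G0 R1 or Clone4 G0 R1 the count was 0, without WT.2 G0 R1 it was 2, and without Clone4 G0 R2 it was 5, ELTD1 and AOX1 among them (limma adjusted p = 0.0144 and 0.0176). The count was also 0 with limma-voom on the recovered reads, which was chosen after seeing the data. In G1/S, SCG5 differed by -0.95 (SE 0.71), which did not pass.

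The next genes in G0 did not pass the threshold, although both KO lines lay beyond all 4 WT lines. Higher in KO were ALDH3B1, an aldehyde dehydrogenase (1.29, SE 0.20), the kinase SGK1 (1.48, SE 0.24), the activin subunit INHBA (1.17, SE 0.19), the syndecan SDC2 (1.22, SE 0.21) and the cathepsin CTSV (1.19, SE 0.21). Lower were ELTD1, an adhesion receptor (-3.72, SE 0.51), aldehyde oxidase AOX1 (-1.98, SE 0.27), GPR176, an orphan receptor (-1.34, SE 0.19), FRMD6 (-0.91, SE 0.13) and RBBP8, a DNA end resection factor (-0.99, SE 0.16). Their adjusted p-values from limma ran from 0.159 to 0.312. Of the 26 gene lists, 4 passed camera's test with the preset correlation, though no member gene passed over all genes. The 26 ATF4 and integrated stress response genes had a median of -0.52 (adjusted p = 0.00037), with 4 values above 0. Their mean log2 level was 9.51 in D7, 9.22 in WT.1, 8.69 in WT.2 and 8.38 in A10 among WT lines, and 8.41 in Clone4 and 8.37 in B9, so D7 and WT.1 carried most of the difference and A10 stood at the KO level. MTHFD2 was at -0.79, ATF4 at -0.39, SLC3A2 at -0.20 and PHGDH at 0.02, though PHGDH stood at -0.16 without library Clone4 G0 R2. The 27 extracellular matrix genes had a median of 0.37 (adjusted p = 0.00037), with THBS1 at 0.97, TIMP1 at 0.54 and SPARC at 0.44. Their mean log2 level was 9.51 in Clone4 and 9.18 in B9, above D7 (9.09), A10 (8.94), WT.2 (8.77) and WT.1 (8.76). Adjusted over the list alone, 2 matrix genes and 0 stress response genes were called. The 13 mitochondrially encoded mRNAs had a median of -0.36 (adjusted p = 0.0019), among them MT-CO3 at -0.42, MT-CO2 at -0.42, MT-CYB at -0.29 and MT-ND4 at -0.28. Their mean in the KO line B9 (13.14) lay above the WT lines D7 (13.00) and WT.2 (13.09), and the WT library WT.1 G0 R1 had a mitochondrial share of 12.8%. MT-CYB stood at 0.04 without line Clone4, and MT-ND4 at 0.04 with R2 alone. The 24 ribosome biogenesis genes had a median of -0.13 (adjusted p = 0.015), with NCL at -0.18, NOP58 at -0.13, NPM1 at -0.12 and DKC1 at -0.11. Their mean was 9.11 in Clone4 and 9.34 in B9, the latter just below the lowest WT line, D7 (9.35). With an estimated correlation all 4 calls were lost, with adjusted p = 0.82 for each.

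In G1/S, no gene differed between KO and WT lines past the threshold in limma or limma-voom, and 613 genes had an unadjusted p under 0.05. For genes with a mean of at least 50 normalized counts, the median half-width of the 95% confidence interval was 0.73 on the log2 scale, against 0.61 in G0. Named without passing (adjusted p = 0.978 for each) were MOXD1 (0.95, SE 0.21), MTERF (1.12, SE 0.30), ZNF365 (1.31, SE 0.36), the collagen COL6A3 (1.13, SE 0.32) and the chloride transporter CLCN3 (1.08, SE 0.31) among the higher. Among the lower were the potassium channel KCNK6 (-3.39, SE 0.61), the noncoding RNA ZFAS1 (-1.21, SE 0.22), MBOAT7 (-0.96, SE 0.21), the kinase NUAK2 (-2.61, SE 0.58) and INSIG1, a regulator of sterol synthesis (-1.0, SE 0.23). NUAK2 and INSIG1 had the opposite sign with R1 alone, at 0.59 and 0.09.

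In G1/S, 3 gene groups passed camera's preset test, each without a called member. The 13 mitochondrially encoded mRNAs had a median of -0.58 (adjusted p = 0.0002), with MT-ND4 at -0.67, MT-CO2 at -0.58, MT-CO3 at -0.40 and MT-CYB at -0.32. The 76 cytosolic ribosomal protein genes had a median of -0.23 (adjusted p = 1.7e-08), with RPL4 at -0.32, RPLP0 at -0.16, RPL3 at -0.14 and RPL8 at -0.08, though RPL8 stood at 0.09 after quantile normalization. The 56 G2 and M phase genes had a median of 0.17 (adjusted p = 0.00063), with CCNB1 at 0.25, TOP2A at 0.25, HN1 at 0.10 and TUBB4B at -0.09. Their mean log2 level was 9.72 in A10, 10.05 in WT.2, 10.11 in WT.1 and 10.20 in D7. It was 10.13 in Clone4 and 10.25 in B9, so A10 carried much of the difference and D7 lay above Clone4. With an estimated correlation, adjusted p = 0.80 for all 3 lists. The WT library A10 G1/S R2, with its 32.3% of mitochondrial counts, entered these values. Without it, a run chosen after seeing the data, the medians were -0.42, -0.12 and 0.11. All 3 lists still passed camera's preset test in that run (adjusted p = 5.7e-05, 0.0015 and 0.013). With an estimated correlation they did not (camera adjusted p = 0.75, 0.81 and 0.76). TUBB4B stood at 0.04 without library B9 G1/S R1.

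Over both stages, 0 genes passed in limma or limma-voom, and 816 had an unadjusted p under 0.05. The 10 genes named here did not pass, with adjusted p-values of 0.492 to 0.879. MOXD1 (1.07, SE 0.18), INHBA (0.76, SE 0.17), the kinase CDK14 (0.96, SE 0.22), SGK1 (1.22, SE 0.29) and ACTBL2 (2.08, SE 0.50) were the higher ones. The microtubule-associated kinase DCLK1 (-1.76, SE 0.28), GPR176 (-0.90, SE 0.18), the cystatin CSTA (-1.66, SE 0.34), KCNK6 (-1.80, SE 0.38) and SCG5 (-1.92, SE 0.40) were the lower ones. With libraries as replicates and line ignored, 30 genes were called. In camera's preset test 5 lists passed: ribosomal proteins (-0.17), mitochondrially encoded mRNAs (-0.44), ATF4 targets (-0.20), ribosome biogenesis (-0.13) and extracellular matrix (0.23). With an estimated correlation their adjusted p-values were 0.77 to 0.81. No member passed. MT-CO2 stood at -0.50, MT-ND4 at -0.48, MT-CO3 at -0.41 and MT-CYB at -0.30. TIMP1 stood at 0.36, THBS1 at 0.32 and SPARC at 0.30, and MTHFD2 at -0.45 and ATF4 at -0.21. RPL4 was at -0.29, DKC1 at -0.23 and NCL at -0.18, while SLC3A2, PHGDH, RPL8, RPLP0, RPL3, NPM1 and NOP58 lay within 0.05 of 0 and changed sign under at least 1 alternative. With R1 alone, the ribosomal protein median was 0.03.

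Stage separated the transcriptomes. G1/S cells had higher levels of genes for S phase entry and DNA replication, and lower levels of genes for cholesterol synthesis, quiescence and histones, than G0 cells of the same line. With an estimated correlation, the cholesterol, quiescence and histone lists passed camera's test and the S phase and replication lists did not (adjusted p = 0.056). Without library A10 G1/S R2, the cholesterol list did not pass that test either (adjusted p = 0.082). Fry's test of a shared direction, which does not compare a list with other genes, called all of these lists. Its adjusted p-values ran from 1.5e-05 for cholesterol synthesis to 0.00028 for homologous recombination and Fanconi genes. Of 15278 genes, 1674 were higher and 1701 lower in G1/S past the threshold over the 6 lines, and 511 and 816 of these changed at least 2-fold. With equal medians per library the split was 2020 higher to 1391 lower. The count of 3375 was 2192 without library A10 G1/S R1, 1672 with R2 alone and 1201 with R1 alone, and 3712 with limma-voom. In this and later runs without A10 G1/S R1, line A10 in G1/S rested on the outlying library A10 G1/S R2 alone. Without A10 G1/S R2 itself the count was 3906. Stage runs without WT.1 G1/S R2 left out line WT.1, which had no other library in G1/S.

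S phase genes rose: 35 of 43 measured members were higher, 0 were lower, and the median was 0.86. Cyclin E2 (CCNE2), which drives S phase entry, was 5.39-fold higher (log2 2.43, SE 0.24, adjusted p = 2.19e-05). The ribonucleotide reductase subunit RRM2 was 3.28-fold, the nuclease EXO1 3.0-fold and the checkpoint mediator CLSPN 2.80-fold higher. Among origin licensing and helicase genes 15 of 21 rose, with ORC1 2.26-fold, CDC45 2.24-fold and MCM10 2.17-fold higher. Among homologous recombination and Fanconi genes 21 of 24 rose, with FANCB 4.39-fold, RAD54B 2.46-fold and RMI1 2.23-fold higher. The camera adjusted p-values were 1.7e-20, 3.2e-10 and 9.1e-12, and with an estimated correlation adjusted p = 0.056 for each. Adjusted over the list alone, 37, 15 and 21 members were higher. The G2 and M phase list did not move one way, with 6 members higher and 8 lower (median -0.01). Its mean log2 level per line ran from 9.83 (A10) to 10.30 (WT.2) in G0 and from 9.72 (A10) to 10.25 (B9) in G1/S. These genes therefore did not set the G0 libraries apart as those of resting cells. CDK1 (1.56-fold) and ANLN (1.55-fold) rose, and GAS2L3 (1.89-fold) and PSRC1 (1.71-fold) fell, though GAS2L3 did not pass without library B9 G1/S R1 (adjusted p = 0.0525).

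Cholesterol synthesis genes fell, with a negative median in every line. Of 24 measured members, 23 were lower and 0 higher, with a median of -1.88 and line medians from -2.11 to -1.63. INSIG1 was 14.8-fold lower (log2 -3.89, SE 0.18, adjusted p = 9.57e-08). The sterol reductase TM7SF2 was 6.23-fold lower, but lay near the floor with a mean log2 level of 3.32, so the size of its fold is uncertain. Camera gave adjusted p = 1.5e-17, and adjusted p = 0.048 with an estimated correlation, which was 0.082 without library A10 G1/S R2. Among quiescence-associated genes 13 of 25 fell and 1 rose (median -1.04, camera adjusted p = 1.6e-06, and adjusted p = 0.034 with an estimated correlation). These included the PI3K inhibitor PIK3IP1 (15.7-fold), the selenoprotein SEPP1 (7.27-fold), the pyruvate dehydrogenase kinase PDK4 (7.15-fold) and TXNIP (5.49-fold). SEPP1, PDK4 and TXNIP lay near the floor, with mean log2 levels of 3.92, 1.98 and 3.45, so the size of their folds is uncertain. PIK3IP1 rested in part on WT.1, where it fell by 8.27 on the log2 scale against 2.08 to 3.87 in the other lines: without library WT.1 G1/S R2 its log2 fold change was -3.11 in place of -3.97, a smaller fall than that of INSIG1. PDK4 did not pass without library Clone4 G0 R1, WT.1 G1/S R2 or Clone4 G1/S R2 (adjusted p = 0.0912, 0.0601 and 0.114). Replication-dependent histone genes also fell, 14 of 24 with 0 higher (median -1.18, camera adjusted p = 5.1e-10, and adjusted p = 0.034 with an estimated correlation). HIST1H2AH was 6.25-fold, HIST1H1E 5.19-fold, HIST1H1A 4.52-fold and HIST1H4I 4.47-fold lower, though HIST1H4I stood at 0.26 with R2 alone and did not pass without library A10 G1/S R1 (adjusted p = 0.111). HIST1H2AH and HIST1H4I were also near the floor, with mean log2 levels of 3.14 and 2.97. Adjusted over the list alone, 23, 16 and 18 members of these lists were lower.

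Immediate early and growth factor response genes fell, 12 of 24 with 1 higher (median -0.68, camera adjusted p = 0.00012, and adjusted p = 0.056 with an estimated correlation). The signalling inhibitor SPRY2 was 8.72-fold, PHLDA1 5.21-fold, FOS 3.77-fold and CTGF 2.98-fold lower. SPRY2 had a low mean log2 level of 4.79, and without library WT.1 G1/S R2 its log2 fold change was -2.51 in place of -3.13. Lysosome and autophagy genes fell, 15 of 24 with 1 higher (median -0.49, camera adjusted p = 3.3e-05, and adjusted p = 0.14 with an estimated correlation). The protease CTSD was 2.02-fold, the cholesterol carrier NPC2 1.95-fold, WIPI1 1.84-fold and HEXA 1.74-fold lower. Ribosome biogenesis genes rose, 10 of 24 with 0 lower (median 0.32, camera adjusted p = 1.6e-05, and adjusted p = 0.056 with an estimated correlation), with WDR12 1.65-fold, UTP20 1.60-fold, MYBBP1A 1.54-fold and NOP16 1.52-fold higher. Heat shock genes gave 6 higher and 2 lower of 15 (median 0.27, camera adjusted p = 0.024, and adjusted p = 0.47 with an estimated correlation). The mitochondrial chaperones HSPE1 (1.76-fold) and HSPD1 (1.72-fold) and the cofactor CHORDC1 (1.52-fold) rose, and HSPA1A fell (1.57-fold). Some of these calls ended when 1 library was left out: that of CHORDC1 (adjusted p = 0.181) and NOP16 (0.0548) without A10 G1/S R1, and that of HSPA1A without D7 G0 R2 (0.0523) or WT.1 G1/S R2 (0.0558). For UTP20, 10 libraries did so (0.148 without A10 G0 R2) and for MYBBP1A 13 (0.119 without A10 G1/S R1). Adjusted over the list alone, 16 growth factor response and 16 lysosome genes were lower, and 12 ribosome biogenesis and 7 heat shock genes were higher.

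Among genes past the threshold with a mean of at least 50 normalized counts and 1 sign in all 6 lines, the largest increases were those of the carbonic anhydrase CA12 (7.0-fold), the metalloproteinase MMP3 (6.20-fold), the vitamin D hydroxylase CYP24A1 (6.17-fold), STYK1 (6.06-fold), the necroptosis effector MLKL (5.86-fold), the receptor TNFRSF9 (5.54-fold), CCNE2, BCYRN1 (5.26-fold), TMEM40 (4.90-fold) and the interferon-induced GTPase GBP1 (4.77-fold). Under the same conditions the largest decreases, besides PIK3IP1 and INSIG1, were those of the polarity gene LLGL2 (12-fold), the phosphatase ALPP (9.14-fold), the lipase PNPLA3 (8.54-fold), the hyaluronan synthase HAS2 (7.99-fold), KLHL24 (7.42-fold), PTP4A3 (7.11-fold), the decoy receptor TNFRSF11B (6.91-fold) and the chemokine CXCL14 (6.87-fold). Besides PIK3IP1, leaving out a single line moved the fold of these by over 1.5 times: HAS2 had a log2 fold change of -2.01 without A10 in place of -3.00, LLGL2 of -2.91 without B9 in place of -3.59 and MMP3 of 1.90 without Clone4 in place of 2.63. Over all 44 alternatives other genes ranged widely too, though each kept its sign. TNFRSF9 ran from 1.56 to 3.63, MLKL from 1.72 to 3.70 and STYK1 from 1.92 to 3.71. PNPLA3 ran from -3.77 to -1.82 and PTP4A3 from -3.63 to -2.12. The limma adjusted p-values of these 20 genes ran from 9.57e-08 to 0.00769. NEAT1 was 1.82-fold lower in G1/S (log2 -0.86, SE 0.22, adjusted p = 0.013), although in line A10 it was higher by 0.40. That rise came from A10 G1/S R2 (11.08), as A10 G1/S R1 (9.91) lay below the G0 mean of A10 (10.10). NEAT1 did not pass without library A10 G1/S R1 (adjusted p = 0.101) or WT.1 G1/S R2 (adjusted p = 0.05). The former run left A10 in G1/S on A10 G1/S R2 alone, and the latter left out line WT.1. MALAT1 was 1.76-fold lower (log2 -0.81, SE 0.18, adjusted p = 0.00588), with a lower value in 6 of 6 lines. Which transcripts of NEAT1 and MALAT1 the poly(A) priming captured was not measured.

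**Figure D2:**
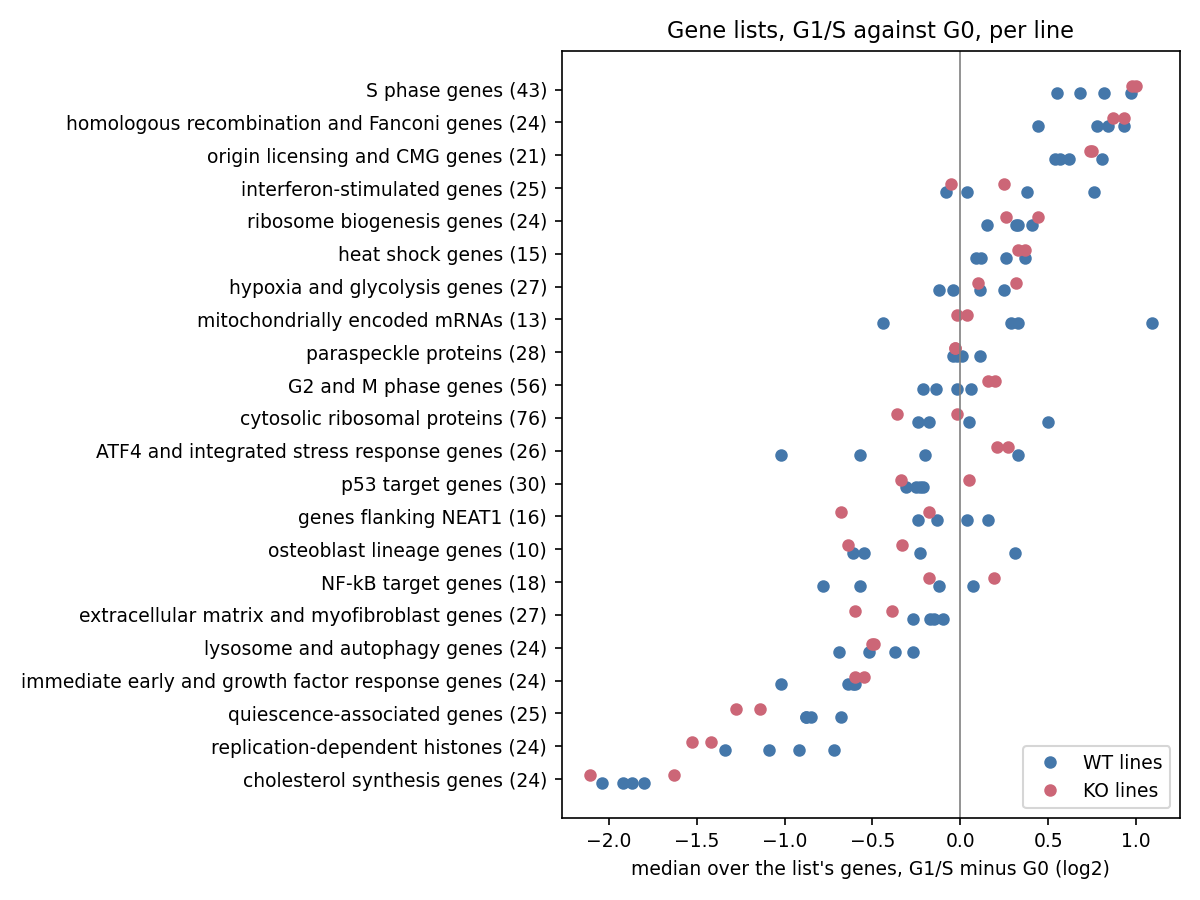
Median G1/S minus G0 difference (log2, horizontal axis) over the measured genes of each list (number in brackets), with 1 point per line, WT in blue and KO in red. Cholesterol synthesis medians lie between -2.11 and -1.63 and S phase medians between 0.55 and 1.0 in the 6 lines.

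The stage comparison was also made within each genotype. In the 4 WT lines 945 genes were higher and 941 lower in G1/S, and in the 2 KO lines 671 were higher and 588 lower. Both genotypes shared 410 of the higher and 357 of the lower genes, and 0 genes were called in opposite directions. Independent lists would share 42 and 36, but both tests used 1 shared spread per gene. A gene of small spread can be called in both for that reason, so 42 and 36 may be too low as a reference. Of the 1886 genes called in WT, 1812 (96.1%) had the same sign in KO. Across genes with a mean of at least 50 normalized counts, the log2 fold changes of both genotypes had a Pearson correlation of 0.69, and over all 15278 genes of 0.54; genes are not independent replicates. These counts moved with single libraries. In WT, the 1886 calls were 778 without A10 G1/S R1 and 867 without WT.1 G1/S R2. The former run left A10 in G1/S on A10 G1/S R2 alone, and the latter left out line WT.1. In KO, the 1259 calls were 300 without A10 G1/S R1, which enters through the shared spread, 717 without D7 G1/S R2, 800 without WT.1 G0 R2 and 817 without A10 G0 R2. With equal medians per library the split was 1130 higher to 791 lower in WT and 871 to 478 in KO.

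**Figure D3:**
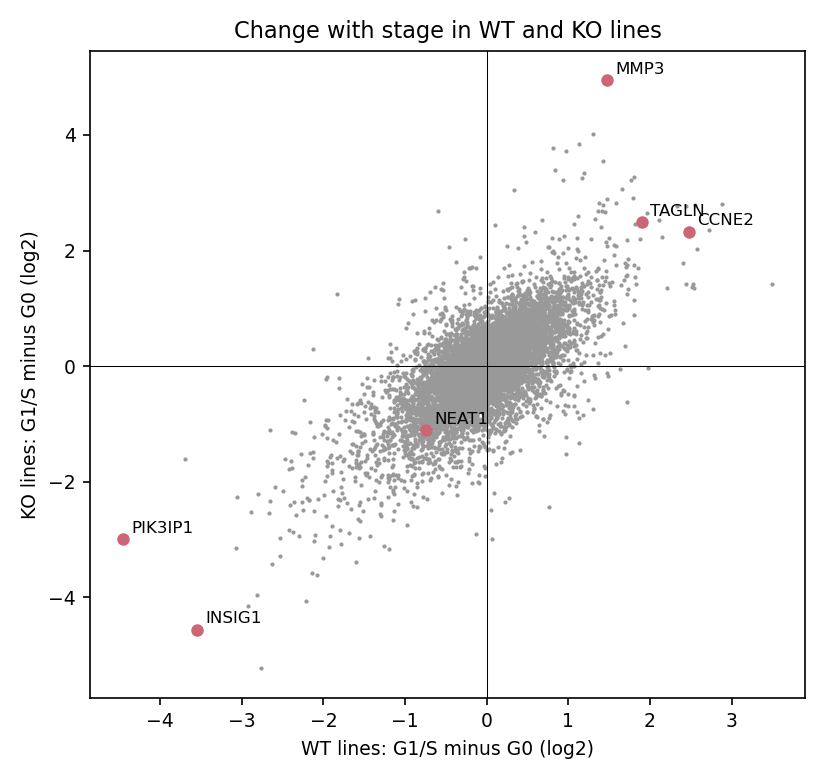
G1/S minus G0 difference (log2) in the WT lines (horizontal axis) against the KO lines (vertical axis), with 1 grey point for each of 9790 genes with a mean of at least 50 normalized counts and a unique symbol, and named genes in red. INSIG1 lies low and CCNE2 and TAGLN lie high on both axes.

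The interaction asked whether the change with stage differed between genotypes. No gene passed in limma or limma-voom, and 1062 had an unadjusted p under 0.05, where 764 would be expected by chance. The same 764 applied to genotype, with 1213 in G0, 613 in G1/S and 816 over both stages. Genes do not vary independently, so such counts can lie above or below 764 without an effect. The genes named here did not pass, with adjusted p-values of 0.586 to 0.687. The G1/S minus G0 change was higher in KO for ELTD1 (3.28, SE 0.53), AOX1 (1.84, SE 0.31), MMP3 (3.48, SE 0.61), the condensin subunit NCAPG2 (1.13, SE 0.23) and MOK (2.55, SE 0.56). It was lower in KO for the lipid phosphatase PPAP2B (-1.87, SE 0.35), ATP11A (-1.34, SE 0.31), the microfibril protein MFAP2 (-0.88, SE 0.20), DCHS1 (-2.56, SE 0.61) and fibulin FBLN1 (-0.72, SE 0.18). Camera's preset test called 8 of 26 lists, 5 without A10 G1/S R2, and 0 with an estimated correlation. The largest list medians among them were those of ATF4 and integrated stress response genes (0.60, adjusted p = 0.0077, and adjusted p = 0.89 with an estimated correlation), genes flanking NEAT1 (-0.46, adjusted p = 0.038, then 0.64) and extracellular matrix genes (-0.43, adjusted p = 0.0077, then 0.64). Line medians of the change were, for stress response genes, 0.33 in A10, -0.20 in WT.2, -0.57 in WT.1 and -1.02 in D7, against 0.21 in B9 and 0.27 in Clone4, and A10 lay above both KO lines. For genes flanking NEAT1 they were -0.68 in B9 and -0.18 in Clone4, against -0.24 in D7, -0.13 in WT.1, 0.04 in WT.2 and 0.16 in A10. For extracellular matrix genes, B9 (-0.60) and Clone4 (-0.39) lay below the WT lines (-0.27 to -0.10). In the other 5 lists the medians were 0.34 for NF-kB targets, 0.25 for homologous recombination and Fanconi genes, 0.24 for G2 and M phase genes, 0.23 for p53 targets and -0.16 for ribosomal proteins. For p53 targets, the line median of B9 (-0.34) lay below all WT lines (-0.31 to -0.21) and that of Clone4 (0.05) above them. For ribosomal proteins, B9 (-0.36) lay below the WT lines (-0.24 to 0.50) and Clone4 (-0.02) among them. For G2 and M phase genes, B9 (0.20) and Clone4 (0.16) lay above the highest WT line, D7 (0.06). Without A10 G1/S R2, genes flanking NEAT1 (median -0.38, adjusted p = 0.099), Fanconi genes (0.15, 0.099) and ribosomal proteins (-0.05, 0.64) did not pass. No member passed. Among stress response genes, MTHFD2 stood at 0.67, SLC3A2 at 0.45, ATF4 at 0.35 and PHGDH at 0.05. Among matrix genes, THBS1 stood at -1.29, TIMP1 at -0.35 and SPARC at -0.29, and next to NEAT1, CAPN1 at -0.59 and POLA2 at 0.14. FANCI stood at 0.56, FANCG at 0.38 and RBBP8 at 0.35 in the Fanconi list, TOP2A at 0.44 in the G2 and M phase list, RRM2B at 0.56 and CCNG1 at 0.29 among p53 targets, and SOD2 at 0.33 and CCL2 at 0.35 among NF-kB targets. The other members named by the rule lay between -0.27 (RPL3) and 0.30 (MALAT1), and several of these signs turned when samples were left out, those of ATF4, PHGDH, TIMP1, POLA2, FANCG and CCL2 included.

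Among the 4 WT lines, limma's F test called 41 genes in G0 and 0 in G1/S, where 1054 had an unadjusted p under 0.05. This test sets lines against the spread of R1 and R2, which were not shown to be separate samples, so its counts are not comparable with those for genotype. The departures of the KO lines B9 and Clone4 from WT were then compared across genes. With separate WT controls for each, the correlation across genes of their differences from WT was 0.06 in G0 (covariance 0.0569), 0.00 in G1/S (0.00483) and 0.01 over both stages (0.00822), against 0.00 in simulated unchanged lines (covariance -0.0011, -0.00078 and -0.0016). When each of the 15 pairs of lines was treated in this way, 2 pairs, the KO pair included, reached the KO pair's covariance in G0, 6 in G1/S and 4 over both stages. In G0 the other pair was WT.1 and WT.2 (0.0582), which may not be independent lines, and the next was D7 and WT.1 (0.0181). The highest covariance was that of D7 and Clone4 in G1/S (0.0508) and over both stages (0.0496).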

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

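Tests of the library A10 G1/S R2 and of genotype for the mitochondrial and ribosomal protein lists were chosen only after their results were seen, and the demand that a bound be passed by more than the spread was added to the former after its first outcome; the other tests in this part were set down before. Of 87 groups of values examined for a value far from the others, 10 had one, where chance gives about 5%.

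The library A10 G1/S R2 lay far above the other WT libraries in G1/S in its mitochondrial share, 32.3% against 4.80% to 8.78%, and in its MT-RNR2 share, 26.9% against 2.43% to 4.71%. Among WT libraries in G0, WT.1 R1 had the highest MT-RNR2 share, 8.89% against 3.19% to 5.82%, and the KO library B9 R1 had 7.91%. This bears on the lower mitochondrially encoded and ribosomal protein mRNAs of the KO lines in G1/S. Without A10 G1/S R2, 72.7% of the mitochondrial median and 54.6% of the ribosomal protein median were left, and leaving out other libraries moved these shares by an SD of 19.5 and 47.6 percentage points, so that library is neither excluded nor shown as the cause; by the bound of 70% alone, as first set, it would have been excluded for the mitochondrial list. Genotype is not decided either: without the library, 1 of the 2 KO lines lay below every WT line for the mitochondrial list, and 0 of 2 for ribosomal proteins. In that run A10 had only R1 and WT.1 only R2 in G1/S, whereas each KO line had both. The mitochondrial share was higher in R1 in 9 of 11 pairs of repeats, and the ribosomal protein share in R2 in 10 of 11. These line counts and kept shares are not adjusted for that imbalance. The library and genotype cannot be told apart as explanations with 2 KO lines.

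The histone decrease went with higher S phase genes, which makes it a pattern to look at again. Counts near the floor are argued against, since the 11 members with a mean of at least 50 normalized counts had a median of -1.10. Reads moving among the 24 measured of 51 listed histone genes would leave their sum alike. That sum was lower in all 6 lines, with -0.77 (log2) as the smallest change. Reads moving to copies outside these 24 genes would lower the sum as well, so this test does not cover them. It also stays open whether the values of the 24 measured genes report only polyadenylated histone transcripts. SMARTseq2 primes on poly(A) tails, and most replication-dependent histone mRNAs lack one. No value here separates such transcripts, and a biological change with stage was not separated from it.

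The decrease of cholesterol synthesis genes did not come from the scaling, as the list median was -1.81 or lower with equal medians and quantile normalization, nor from one set of repeats, as it was -1.69 or lower with R1 or R2 left out. All 6 lines were sampled in both stages, and the way cells were brought to G0 or G1/S went with the stage, so stage and a difference in medium or serum cannot be told apart.

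The count of genes by stage exceeded chance if the 6 lines are independent. Of 32 sign assignments of the 6 line differences, only 1, the real one, gave 3375 genes, and the highest of the others gave 0. WT.1 and WT.2 may not be independent lines. Counted as 1 line, they would leave too few assignments for a share under 0.05, so the test would then not decide. For WT alone, 8 assignments are too few for a share under 0.05; the real count was 1886 and the highest other 0. For genotype, 15 splits of the lines are too few as well. In G0, the real count was 1 and the highest other 12, from the split of D7 and Clone4 against the rest, and 2 splits reached the real count. No test tied these 12 genes to a structure among the lines, and the departures of D7 and Clone4 from the other lines had a covariance of 0.00639 across genes. In G1/S and for the interaction, the real count and the highest other were 0, so 15 of 15 splits reached it. Over both stages, the real count was 0 and the highest other 4.

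Among the named genes, 3 had a line whose G1/S minus G0 difference lay far from the other 5: PIK3IP1 in WT.1 (-8.27 against -3.87 to -2.08), HAS2 in A10 (-7.94 against -3.19 to -1.03) and CXCL14 in Clone4 (-4.57 against -2.64 to -1.98). Among WT lines, ALDH3B1 was highest in A10 in G0 (9.05 against 8.62 to 8.66) and SDC2 in WT.2 in G0 (9.25 against 9.13 to 9.14). Over both stages, A10 was lowest for SGK1 (6.41 against 7.15 to 7.25) and highest for KCNK6 (7.15 against 6.41 to 6.49).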

How the results depend on the processing

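Limma-voom and the runs of the lists, of the differences among WT lines and of the KO line agreement without library A10 G1/S R2 were chosen after seeing the data; the other alternatives were planned. SCG5 kept its sign in 44 of 44 alternatives and passed the threshold in 32, with adjusted p-values of 0.0033 to 0.317. Of 107 genes named for stage, 55 passed in all alternatives, and 1 changed sign in 1. The cause of a change was not tested, except that single repeats and left-out lines leave fewer samples. Depth, 5.34 M to 13.5 M reads per library, limits genes near the floor most.

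Counts of genes past the threshold moved by over 1.5 times in these cases. For genotype in G0 (1 in the main test) they were 60 without a filter on low values, 2 with a pseudocount of 10, 0 with a prior without trend, 8 with line ignored, 0 with line correlation, 0 with WT.1 and WT.2 as 1 line and 0 with limma-voom. Leaving out lines, libraries or repeats gave 0 to 8. For genotype in G1/S (0), they were 72 without a filter, 1 without trend, 2 with line ignored and 1 with line correlation, and 0 to 1 with samples left out. Over both stages (0), they were 30 with line ignored and 5 with line correlation, and 0 to 5 with samples left out. The interaction (0) gave 0 to 1. Stage over all lines (3375) gave 2099 without trend, and 1201 to 3906 with samples left out. Stage in WT (1886) gave 985 without a filter, 370 without trend, 1032 with WT.1 and WT.2 as 1 line, and 220 to 2435. Stage in KO (1259) gave 597 without a filter, 30 without trend, 2062 with limma-voom, and 117 to 1723. With lines of a group left out, a lone line was assumed to vary like the others.

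The labels do not say what libraries with the same repeat number share. The R1 minus R2 differences of 11 pairs of repeats gave 55 correlations of -0.081 to 0.21 (median 0.095), and 27 were over 0.1, so the rule that all exceed 0.1 was not met and the numbers were not used to pair samples. Hints of a shared repeat difference were seen in the data. For 11 of 11 pairs, the largest positive correlation with another pair exceeded the largest negative one in size. With correlations of -0.081 to 0.21, this adds little to their median. The ribosomal protein share was higher in R2 in 10 of 11, and the mitochondrial share was higher in R1 in 9 of 11. These counts were chosen after seeing the data. With the number as a replicate block on libraries, the counts were 8 for genotype in G0, 1 in G1/S, 3 over both stages, 3743 for stage and 0 for the interaction, and on line means 1, 0, 0, 3251 and 0.

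Differences among WT lines in G0 (41) came to 136 without a filter, 122 with a filter at 50 and 63 with equal medians, and in G1/S (0) to 952, 3 and 1. Lists past the threshold for genotype in G0 (4) were 0 with an estimated correlation, 0 with fry's test of a shared direction and 7 without a filter. In G1/S (3) and over both stages (5) they were 0 and 0. For the interaction (8) they were 0, 0 and, without A10 G1/S R2, 5, and for stage (10) they were 3 with an estimated correlation and 10 with fry's test of a shared direction. With an estimated correlation and without A10 G1/S R2, also chosen after seeing the data, they were 2 for stage, histones and quiescence (adjusted p = 0.036 for each), and 0 in the other 4 comparisons. Fry's test of change in either direction, which does not compare a list with other genes, called 4 lists for genotype in G0: quiescence-associated (adjusted p = 0.00036), immediate early (0.0011), origin licensing (0.0049) and p53 target genes (0.036). It called 1 in G1/S, cholesterol synthesis (0.0025), 0 over both stages, 25 for stage and 3 for the interaction: endothelial markers (0.0052), homologous recombination and Fanconi genes (0.012) and lysosome genes (0.027). The covariance of the KO lines with all WT lines shared was 0.194 in G0, 0.189 in G1/S and 0.106 over both stages, against 0.14, 0.18 and 0.095 in simulated unchanged lines. With separate WT controls, the covariance in G1/S was 0.00483, and -0.00712 without A10 G1/S R2.

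Signs changed for these genes, none of which passed in its comparison except HIST1H4I. With the replicate block on line means, MALAT1 stood at -0.04 for genotype in G1/S; RPL8 stood at 0.00, RPLP0 at 0.01 and RPL3 at 0.02 for genotype over both stages; HN1 stood at 0.03 for the interaction. With limma-voom, MALAT1 stood at -0.08 and RPL8 at 0.01 for genotype in G1/S; NEAT1 stood at 0.06, PHGDH at -0.01, RPL3 at 0.02 and NOP58 at 0.07 for genotype over both stages; PHGDH stood at -0.03 for genotype in G0; HN1 stood at 0.05, NFKBIA at 0.01, LIF at 0.27, RPL8 at 0.05 and RPL4 at 0.08 for the interaction. With quantile normalization, RPL8 stood at 0.09 for genotype in G1/S; RPL8 stood at 0.04, RPLP0 at 0.03, RPL3 at 0.04 and NOP58 at 0.01 for genotype over both stages; DPF2 stood at -0.02, RPL8 at 0.10 and RPL4 at 0.04 for the interaction. With equal medians, RPL3 stood at 0.00 for genotype over both stages; HN1 stood at 0.02 and FANCD2 at 0.00 for the interaction. With the replicate block on libraries, RPL3 stood at 0.00 and NOP58 at 0.00 for genotype over both stages; DPF2 stood at -0.01 and HN1 at 0.02 for the interaction. With WT.1 and WT.2 as 1 line, NOP58 stood at 0.03 for genotype over both stages; DPF2 stood at -0.05 and HN1 at 0.03 for the interaction. With line ignored, DPF2 stood at -0.03 and NFKBIA at 0.01 for the interaction. With line correlation, DPF2 stood at -0.03 for the interaction.

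The lowest and highest values with lines, libraries or repeats left out were these. For genotype in G0, NEAT1 ran from -0.26 to 0.61, MALAT1 from -0.73 to 0.31, PHGDH from -0.16 to 0.20, NPM1 from -0.27 to 0.03 and MT-CYB from -0.61 to 0.04. MT-ND4 ran from -0.61 to 0.04. For genotype in G1/S, NUAK2 ran from -5.21 to 0.59, INSIG1 from -1.98 to 0.09, NEAT1 from -0.71 to 0.25, MALAT1 from -0.17 to 0.36 and TUBB4B from -0.22 to 0.04. CCNB1 ran from -0.05 to 0.56, HN1 from -0.08 to 0.28, RPL8 from -0.21 to 0.05 and RPLP0 from -0.40 to 0.10. For genotype over both stages, NEAT1 ran from -0.17 to 0.25, MALAT1 from -0.36 to 0.19, SLC3A2 from -0.31 to 0.35, PHGDH from -0.05 to 0.16 and SPARC from -0.03 to 0.63. RPL8 ran from -0.13 to 0.06, RPLP0 from -0.20 to 0.18, RPL3 from -0.05 to 0.07, NPM1 from -0.12 to 0.25 and NOP58 from -0.26 to 0.20. For the interaction, NEAT1 ran from -1.32 to 0.46, MALAT1 from -0.28 to 0.89, DPF2 from -0.20 to 0.22, POLA2 from -0.25 to 0.52 and TUBB4B from -0.30 to 0.13. CCNB1 ran from -0.15 to 0.35, HN1 from -0.21 to 0.15, FANCD2 from -0.45 to 0.37, FANCG from -0.02 to 0.86 and CDKN1A from -0.34 to 0.21. PLK2 ran from -0.09 to 0.41, PHGDH from -0.17 to 0.23, ATF4 from -0.15 to 0.66, CCL2 from -0.15 to 0.84 and NFKBIA from -0.40 to 0.22. LIF ran from -0.62 to 0.44, TIMP1 from -0.65 to 0.08, RPL8 from -0.26 to 0.07 and RPL4 from -0.20 to 0.11. For stage, HIST1H4I ran from -4.75 to 0.26.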

Other observations

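The lists were fixed before the data were examined, and the run without library A10 G1/S R2 was chosen after its values were seen. Several gene groups changed in both directions with stage and gave no list call. Of 27 extracellular matrix genes, 5 were higher and 11 lower in G1/S. The actin-binding protein TAGLN rose 4.28-fold, and the proteoglycans DCN and LUM fell 5.01-fold and 3.77-fold and the collagen COL3A1 3.31-fold. DCN lay near the floor, with a mean log2 level of 2.01, so the size of its fold is uncertain. Of 10 osteoblast lineage genes, 2 were higher, ALPL (4.10-fold) and SPP1 (2.30-fold), and 3 lower, among them TNFRSF11B (6.91-fold) and RUNX2 (2.54-fold). Of 26 ATF4 and integrated stress response genes, 2 were higher and 5 lower, among them DDIT4 (2.77-fold), DDIT3 (2.57-fold), TRIB3 (2.26-fold) and NUPR1 (2.14-fold), all lower. Among 25 interferon-stimulated genes USP18 (3.0-fold) and OAS1 (2.31-fold) rose and IFIT1 (3.57-fold) and IRF9 (2.67-fold) fell, with 5 higher and 3 lower in all. Of 27 hypoxia and glycolysis genes 4 rose, such as ENO2 (2.16-fold) and BNIP3 (2.05-fold), and 4 fell, such as ALDOC (2.73-fold) and PFKFB4 (2.35-fold). Leaving out 1 library ended the call of USP18 for 13 libraries (adjusted p = 0.14 without B9 G0 R1), of IFIT1 for 7 (0.129 without Clone4 G1/S R2), of RUNX2 for 4 (0.0948 without WT.2 G1/S R2), of OAS1 for 2 (0.0765 without Clone4 G0 R1), of DCN without A10 G0 R2 (0.0572) and of ALPL without WT.1 G1/S R2 (0.0725). The log2 fold change of IFIT1, -1.84, was -2.43 without Clone4 G1/S R1 and -1.24 without Clone4 G1/S R2, and that of USP18, 1.59, was 0.92 without WT.1 G1/S R2.

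Of 28 paraspeckle proteins, 3 were higher and 3 lower, with NUDT21 1.54-fold, FAM98A 1.41-fold and RBM3 1.31-fold higher and CIRBP 1.41-fold lower. Of 16 genes flanking NEAT1, POLA2, a subunit of DNA polymerase alpha, rose 2.32-fold, and MALAT1 and CAPN1 (1.41-fold) fell. Of 30 p53 target genes 2 were higher and 7 lower, among them TP53INP1 (2.12-fold), PERP (1.79-fold) and PLK3 (1.60-fold) lower and C12orf5 (1.46-fold) higher. Of 18 NF-kB target genes CCL2 (3.48-fold) and NFKBIA (1.45-fold) fell and SOD2 (1.32-fold) rose. Of 76 ribosomal protein genes 2 were higher and 12 lower, with RPL13A 1.78-fold, RPS27 1.55-fold, RPL3 1.5-fold and RPL31 1.38-fold lower; without A10 G1/S R2 there were 3 higher and 23 lower, and the list passed camera's preset test (median -0.13, adjusted p = 0.034, and adjusted p = 0.82 with an estimated correlation). Of 13 mitochondrially encoded mRNAs MT-ND2 (1.43-fold) and MT-CYB (1.32-fold) rose. Markers of other cell types showed no list call: 1 of 7 epithelial genes fell (KRT14, 3.20-fold). Of 6 leukocyte genes CD68 (7.80-fold) and CORO1A (2.53-fold) rose and PTPRC (11.8-fold) fell. The size of the PTPRC fold is uncertain, as its log2 fold change ran from -4.08 to -1.58 over the 43 alternatives that tested it. Of 6 endothelial genes ERG (4.61-fold) rose and VWF (4.98-fold) and EGFL7 (1.42-fold) fell. The size of the VWF fold is uncertain too, with log2 fold changes from -3.66 to -0.98 over the 43 alternatives that tested it. Of 8 neural genes SNAP25 (2.41-fold) and TUBB3 (1.49-fold) rose and MAP2 (4.78-fold) fell. Leaving out 1 library ended the call of VWF for 16 libraries (adjusted p = 0.121 without D7 G0 R1), of FAM98A for 13 (0.134 without A10 G1/S R1), of PLK3 for 10 (0.118 without A10 G1/S R1), of MT-ND2 for 8 (0.243 without WT.1 G0 R2), and of CAPN1, SOD2 and MT-CYB for 7 each (0.114 without WT.2 G1/S R1, 0.224 without WT.1 G0 R1 and 0.133 without WT.2 G0 R2). It ended that of CIRBP for 6 (0.109 without WT.2 G1/S R1), of EGFL7 for 5 (0.0847 without D7 G1/S R1), of RBM3 for 4 (0.124 without WT.1 G0 R2) and of RPL31 for 2 (0.207 without A10 G1/S R1).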
